A study of Mus musculus with 2 samples.

How the data were processed

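Gene expression was measured in a mouse glioblastoma stem cell line, a line of tumour cells kept as floating neurospheres in serum-free medium with EGF and bFGF. Per the labels' protocols, the line came from brain tumours made de novo with a Sleeping Beauty transposon. It was transduced with a lentivirus carrying either a non-target control shRNA or an shRNA against Gli2, and stably transduced cells were used. Each of the 2 groups holds 1 array, so the series has no replicates.

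Per the labels' protocols, total RNA was labelled with Cy3 by a low-input amplification kit and hybridised to 1-colour Agilent arrays. Per the file headers, the scans were read with Agilent Feature Extraction 12.1.0.3 under protocol GE1_1200_Jun14 on design 074809, whose grid refers to mouse build mm9. Both arrays were on 1 slide and in 1 scan, so neither slide nor scan differs between the groups. The deposited scanner files hold, per the file headers, the background-subtracted processed intensity of each spot, its error as estimated by the software, the median and background intensities, and flags. The authors' deposited value table holds 56743 rows on a log2 scale with no stated centring. Compared with the scanner values, each of its columns was the log2 processed intensity minus 1 constant, 8.36 for the control array and 8.64 for the Gli2 shRNA array, which puts each column's 75th percentile at 0. The column medians of that table were -3.55 and -3.69.

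Each array held 62976 spots, of which 59305 were not controls, for 56605 probes. Spots that the software marked as non-uniform or as population outliers were left out (126 on the control array, 120 on the Gli2 shRNA array), and no spot was saturated. That left 56595 probes. Spots of the same probe were averaged on the log2 scale. The values used throughout are the log2 processed intensity minus the 75th percentile of the non-control probes of the same array (a signal of 329 on the control array and 399 on the Gli2 shRNA array). A difference is the Gli2 shRNA value minus the control value.

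A probe was measured on an array when the software marked it as well above background, which held for 33694 probes (59.5%) on the control array and 32334 (57.1%) on the Gli2 shRNA array. For a probe measured on 1 array only, a lower bound of the difference was taken. Its dim side was set to the higher of the probe's own value and the lowest signal well above background on that array (12.8 on the control array, 15.2 on the Gli2 shRNA array). Such results are written as "at least N-fold". Where the probe's own value was the higher, the bound equals the difference itself, and the true fold can be smaller by the software error.

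Probes were named by matching their RefSeq accessions, without versions, to the gene table of assembly GRCm38.p6, which was used for names, chromosomes and neighbouring genes only, and none of whose coordinates are given. 34560 probes matched 1 gene, for 23784 genes, and 22035 probes stayed unnamed here. 8292 genes had several probes, and each of these was represented by its brightest probe. For a named gene, other probes well above background on both arrays are given where they went another way or, if the gene was past 2-fold, where they were within 2-fold.

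With 1 array per group there is no test and no p-value. Genes were counted by a fixed size rule of 2-fold, among genes measured on both arrays, and apart from these by the lower bound among genes measured on 1. The error printed beside a gene's log2 difference is the software's own error of both spots, carried over to the log2 difference. It covers the spot and not the cultures. Its median over genes was 0.204, and most bright genes had nearly this same value. It is thus an error modelled by the software and not a spread measured on those spots. 300 probes had 10 spots per array. Over the 293 of these that were well above background on both arrays, the median SD between spots was 0.04 on the log2 scale on each array, at a median signal of 65733, far brighter than most genes. Precision across cultures is unknown, because the number of arrays limits it.

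28 gene lists (838 entries, with some genes in several lists) were fixed before the data were examined, and so were the size rule, the rule for named genes and the alternatives, apart from those named below as added. For each list, the median log2 difference of its members measured on at least 1 array was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Members measured on 1 array entered at their lower bound. A list is said to stand apart when its median lay outside the central 95% of the random lists. This describes these 2 arrays and is not a test across cultures. Lists with fewer than 5 measured members were to get no percentile.

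The genes named are Gli2, the 12 genes in each direction with the highest differences on both arrays, the 4 in each direction with the highest bounds on 1 array, up to 3 genes in each direction per list, and 17 fixed genes of the Hedgehog pathway, cell state and cell cycle. Both the 12 and the 4 genes had to have a symbol that is not a clone or model name, so a higher bound of such a gene is passed over. The 12 genes also had to have all measured probes going the same way, and a 2-fold difference under normexp too. List members within 2-fold, or measured on 1 array, are also given as examples, and these were chosen after their values were seen. Some genes that the rule or the examples would take are not reported here.

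The alternatives were normexp background correction, quantile normalization, scaling on the median of each array, cyclic loess, the authors' processed values, no filter and a stricter filter on dim probes (a signal of at least 100 on 1 array or more), the mean of all measured probes of a gene, size rules of 1.5-fold and 3-fold, and list members measured on both arrays only. Normexp (offset 50) was planned on the mean spot signal and was run on the median spot signal with the median background, which are the columns used here. Scaling on spike-in probes, matching of random lists on gene density (protein-coding genes within 1 Mb, with 10 bins each for expression and density), a check of that matching with the same bins and no density, random lists not matched on expression, 4 further gene lists and the alternatives for chromosomes were added after the data had been seen.

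The calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. They were tested on simulated data, in which a second array was drawn from the control array and 200 genes were given known folds. The noise was normal, with the robust spread of the real differences at each level of expression. Of the 50 genes planted at each size, 92% at 2.5-fold and 100% at 3-fold were called in the right direction, and 6% at 1.5-fold, over 15506 genes. Of 15276 genes left unplanted, 66 (0.43%) passed the 2-fold rule. Such noise leaves out the tails of the real differences, and no probe could drop out on 1 array. This share is therefore not a rate of false calls on the real arrays. A list of 30 genes shifted by 0.3 on the log2 scale lay at percentile 100, and 4.6% of 500 lists without a shift lay outside the central 95%.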

Results

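To ask how suppression of Gli2, a zinc finger transcription factor through which the Hedgehog pathway acts on its target genes, alters gene expression in glioblastoma stem cells, a mouse glioblastoma stem cell line carrying a Gli2 shRNA was compared with the same line carrying a non-target control shRNA. The line grows as neurospheres and came from a transposon-induced brain tumour. 1 array was hybridised per group, so no value below has a replicate check, and the errors given are those of the scanner software for the spots. Of 23784 named genes, 14563 were measured on both arrays, 931 on the control array only and 476 on the Gli2 shRNA array only. For 7798 genes no probe was well above background on either array.

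Gli2 was lower in the Gli2 shRNA array, at 48.7% of its control level. Its probe (RefSeq NM_001081125, chromosome 1) gave a processed signal of 98.1 in the control and 57.9 in the Gli2 shRNA array, a scaled log2 difference of -1.04 ± 0.22, or 2.05-fold. Gli1 and Gli3, the other Gli transcription factors, differed by -0.32 ± 0.21 and -0.60 ± 0.20. Ptch1, the Hedgehog receptor and a target gene of the pathway, differed by -0.69 ± 0.22 on its brighter probe and by -0.04 ± 0.26 on its other probe. The Gli2 value rests on 1 probe of moderate brightness, and after normexp background correction, which pulls differences of dim probes toward 0, its difference was -0.64. With median scaling (-0.90) and cyclic loess (-0.95) it also fell short of 2-fold.

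**Figure D1:**
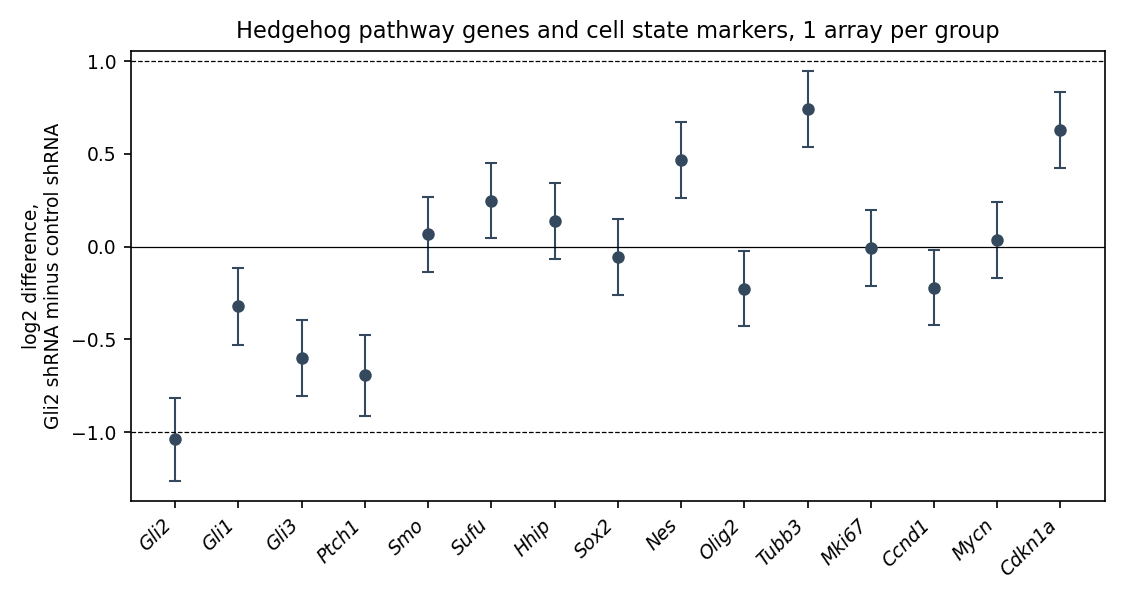
Log2 difference between the Gli2 shRNA and the control array (vertical axis, 1 array per group) of Hedgehog pathway genes and cell state markers measured on both arrays. Points are the brightest probe of each gene, bars are the scanner software's error of the difference, and dashed lines mark 2-fold. Gli2 lies at -1.04, and the other genes drawn lie between the dashed lines.

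Most other parts of the Hedgehog pathway had similar levels in both arrays. Smo, the signal transducer of the pathway, differed by 0.07 ± 0.20. Hhip, a Hedgehog-binding protein induced by the pathway, differed by 0.14 ± 0.20. Sufu, which holds Gli proteins in the cytoplasm, differed by 0.25 ± 0.20 on its brightest probe and by -0.49 ± 0.29 on another. Evc, a protein of the ciliary base that acts with Smo, was higher by 0.91 ± 0.25, short of 2-fold. Of the 26 measured pathway components, Gli2 was the member past 2-fold, 15 lay above 0 and 11 below. The list median of 0.05 was at percentile 63.9 of matched random lists.

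Genes described as targets of GLI proteins were lower as a group. Of 27 measured members, 17 lay below 0, and the median of -0.17 was at percentile 0.86 of matched random lists, whose central 95% ran from -0.15 to 0.14. The lower members included Sfrp1, a secreted Wnt antagonist, at least 2.04-fold lower and measured on the control array only. Prdm1, a transcriptional repressor, differed by -0.62 ± 0.20, Nkx2-2, a ventral neural tube homeobox gene, by -0.55 ± 0.20, Sox9 by -0.47 ± 0.20 and Pdgfra by -0.41 ± 0.21. 10 members lay above 0. Of these Jag2, a Notch ligand, was 3.21-fold higher at a low signal (16.1 in the control), and Foxf1 differed by 0.82 ± 0.21. The proliferation genes Ccnd1 (-0.22 ± 0.20) and Mycn (0.03 ± 0.20) were within 2-fold. With normexp the list was at percentile 6.94, with members measured on both arrays at 5.41 and without the filter on dim probes at 44.8, so that under these 3 settings it did not stand apart.

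Across all genes, most were at similar levels in both arrays. 268 genes were higher and 260 lower by 2-fold or more in the Gli2 shRNA array, 3.63% of the 14563 genes measured on both, and 93 genes differed by 3-fold or more. These counts depend on the processing: normexp gave 67 higher and 100 lower, and median scaling 384 and 176. The other 14035 genes (96.4%) lay within 2-fold. The SD of the log2 difference over genes was 0.42, and the levels on the arrays correlated across genes with r = 0.99, where genes are not independent replicates. A further 148 genes measured on the Gli2 shRNA array only were at least 2-fold higher, and 169 measured on the control array only were at least 2-fold lower. Of the genes past 2-fold, 137 had several measured probes, and for 120 of them (87.6%) every measured probe went the same way. Higher genes made up 50.8% of the calls, 68.6% with median scaling, 61.4% with cyclic loess and 40.1% with normexp, and median scaling raised the median difference of all genes by 0.14. The genes of highest difference described next are past 2-fold with normexp by the rule that chose them. Of the other 23 genes past 2-fold that the rule names, 14 were within 2-fold with normexp: Gli2 (-0.64), Itga6 (-0.97), Apoe (0.94), Slc2a3 (0.89), Dkk3 (0.70), Eda2r (-0.60), Ifit2 (-0.55), Nefh (0.55), Anpep (0.49), Jag2 (0.45), Sfrp2 (0.45), Tap2 (0.29), Tgfb1 (0.13) and Car12 (0.13). Genes measured on 1 array only are not in this count.

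**Figure D2:**
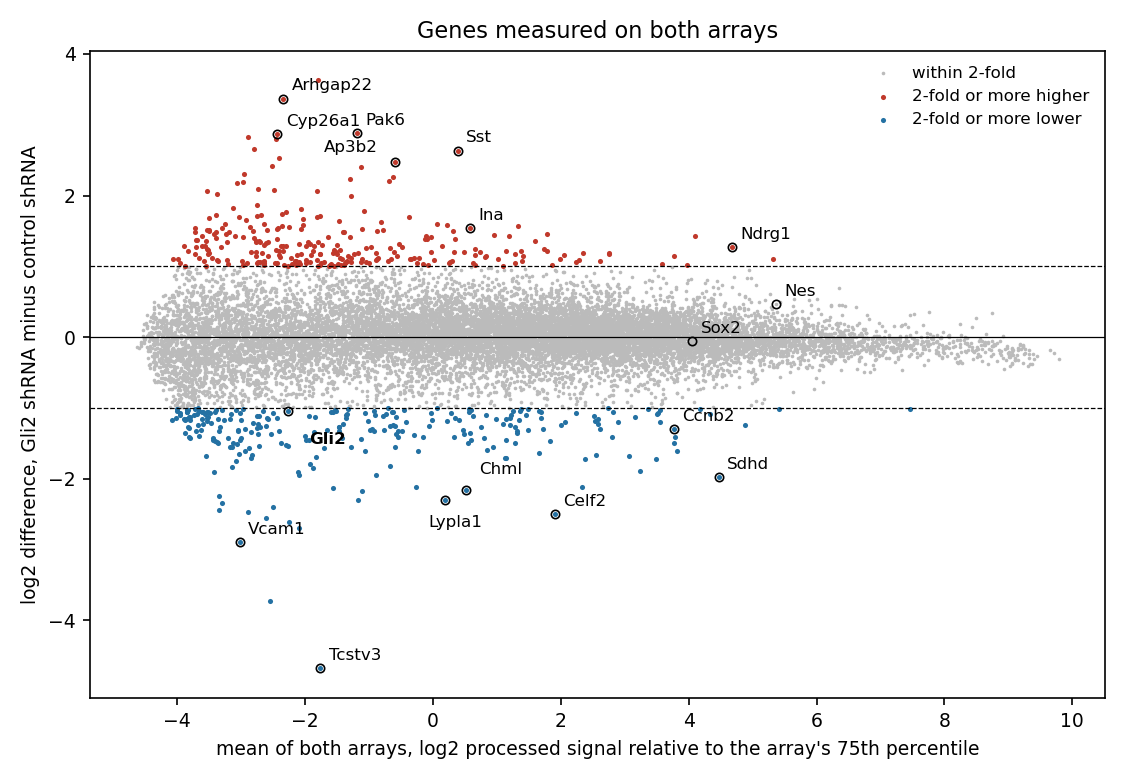
Log2 difference between the Gli2 shRNA and the control array (vertical axis) against the mean log2 level of both arrays (horizontal axis, relative to each array's 75th percentile) for the 14563 genes measured on both arrays. Each point is 1 gene, dashed lines mark 2-fold, and circles mark genes named in the text. 268 genes lie on or above the upper line and 260 on or below the lower line, with Gli2 close to the lower line.

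The genes with the highest differences in the Gli2 shRNA array included signalling genes, neuropeptide and vesicle genes and an enzyme of retinoic acid breakdown. Arhgap22, a Rac GTPase-activating protein, was 10.3-fold higher (3.37 ± 0.30), and Pak6, a p21-activated kinase, 7.38-fold higher (2.88 ± 0.22). Cyp26a1, which breaks down retinoic acid, was 7.29-fold higher, and the serine protease-like gene Prss35 6.99-fold. Sst, the neuropeptide somatostatin, was 6.20-fold higher with a signal of 173 in the control and 1301 in the Gli2 shRNA array. Ap3b2, the neuronal subunit of an adaptor complex of vesicles, was 5.53-fold higher, and the secretory granule protein gene Scg2 5.28-fold. Stac2 (5.32-fold), Adcy1 (3.96-fold), an adenylate cyclase of neurons, and Azin2 (3.43-fold), a regulator of polyamine synthesis, followed. Tmem178b and Sh2d5 were 4.73-fold and 4.20-fold higher on the brighter probe, but their other probes gave log2 differences of 0.74 and 0.15. The fold sizes of dim genes are uncertain. Arhgap22 (20.2), Cyp26a1 (22.6), Prss35 (22.6) and Stac2 (24.9) were near the lowest signal well above background on the control array (12.8). With normexp their log2 differences were 1.60, 1.25, 1.32 and 1.11.

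Among genes measured on the Gli2 shRNA array only, Dock5, a Rac exchange factor, was at least 35.4-fold higher on its brightest probe, where the signal was 8.06 in the control and 549 in the Gli2 shRNA array. A second Dock5 probe, measured on both arrays, differed by 0.51 ± 0.25. Nrap, an actin-binding protein of muscle, was at least 35.2-fold higher on 1 probe and lower on its other probe, which was near background (27.3 and 16.5). Cstdc5 and Slc44a3, each with 1 probe, were at least 28.3-fold and 23.4-fold higher.

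The genes with the lowest differences included adhesion and cytokine genes, RNA-binding and lipid-processing proteins and a mitochondrial coactivator. Tcstv3, a gene of the mouse 2-cell embryo, was 25.6-fold lower (-4.68 ± 0.30), with a signal of 492 in the control and 23.3 in the Gli2 shRNA array. Vcam1, an adhesion molecule of astrocytes, neural stem cells and activated endothelium, was 7.45-fold lower, and the alarmin cytokine Il33 4.36-fold. Celf2, an RNA-binding splicing regulator, was 5.67-fold lower on its brightest probe (2935 and 628), and its 3 probes measured on both arrays gave -2.74 to -1.33. Lypla1, an acyl-protein thioesterase, was 4.94-fold lower on its brighter probe and differed by -0.93 on its other probe, and Chml, a Rab escort protein, was 4.47-fold lower. Ppargc1a, a coactivator of mitochondrial genes, was 4.93-fold lower. Zcchc12 (6.48-fold), DXBay18 (6.08-fold), the neuronal adhesion gene Cntnap2 (5.55-fold), Rgs8 (4.51-fold), a regulator of G protein signalling, and Sel1l3 (4.38-fold) were also lower. Tcstv3 (23.3), Vcam1 (18.0) and Cntnap2 (22.8) were near the lowest signal well above background on the Gli2 shRNA array (15.2). With normexp their log2 differences were -2.83, -1.31 and -1.17. Among genes measured on the control array only, and without those under a clone or model name, Tprg, Nat8f5, Olfr610 and Mfsd6l were lower by lower bounds of 10.7-fold (Mfsd6l) to 12.5-fold (Tprg).

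Most stem cell markers were within 2-fold. Sox2, a transcription factor of neural stem cells, differed by -0.06 ± 0.20, the intermediate filament gene Nes by 0.47 ± 0.20 and Olig2 by -0.23 ± 0.20. Itga6, a laminin receptor used to enrich glioblastoma stem cells, was 2.02-fold lower on its brightest probe. Nr2e1, a nuclear receptor of neural stem cells measured on the control array only, was 2.14-fold lower. Its log2 difference was -1.10 ± 0.44, and -0.41 with normexp. Cd44 (-0.80 ± 0.20) and Aldh1a3 (0.94 ± 0.20) fell short of 2-fold. Prom1, which encodes CD133, was near background (14.6 and 20.2). The 33 measured members had a median of -0.06, at percentile 12.7.

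Markers of differentiated neural cells were mixed. Among 26 measured neuronal markers, 4 were past 2-fold and higher on both arrays: Sst, the neurofilament gene Nefh (3.04-fold), the internexin gene Ina (2.90-fold) and the enolase gene Eno2 (2.66-fold). Reln, an extracellular guidance protein measured on the Gli2 shRNA array only, was at least 2.76-fold higher, but its log2 difference was 0.24 with normexp. Tubb3, a tubulin of neurons, differed by 0.74 ± 0.20, and Ncam1 by -0.85 ± 0.20. The migrating neuroblast marker Dcx differed by -0.93 ± 0.20 on its brighter probe and by 2.75 on its other probe, and has no settled direction. The neuronal list median of 0.08 was at percentile 79.4. Of 17 astrocyte markers, 12 lay below 0, with Mlc1, an astrocyte membrane protein, 2.11-fold lower, Glul at -0.69 ± 0.20 and Aldh1l1 at -0.62 ± 0.21. Apoe, the lipid carrier of astrocytes, was 2.01-fold higher (0.93 on its other probe). That list had a median of -0.19 at percentile 2.92, just inside the central 95%, and it stood apart in 5 of the 8 alternatives that do more than shift all genes alike. Gfap was near background, with 1 probe lower and the other higher. None of the 14 oligodendrocyte lineage markers was past 2-fold (median -0.09, percentile 25.6).

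Genes of DNA replication were slightly lower as a group. Of 38 measured S phase genes, 28 lay below 0, with a median of -0.14 at percentile 0.25. Ccne2, the cyclin E2 gene, was at least 3.04-fold lower and measured on the control array only, Chaf1b, a histone chaperone subunit, differed by -0.55 ± 0.20 and Tyms, the thymidylate synthase gene, by -0.35 ± 0.20. E2f1 went the other way, at 0.40 ± 0.20. The mitosis list was within the random range (median -0.08, percentile 3.84), but stood apart in 4 of the 8 alternatives that do more than shift all genes alike. Its lowest member was Ccnb2, the cyclin B2 gene, 2.46-fold lower, and Mki67, the proliferation marker, differed by -0.01 ± 0.20.

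Cholesterol synthesis genes were lower together by small amounts. 20 of 23 measured members lay below 0 and none was past 2-fold, with a median of -0.19 at percentile 0.11. Hmgcs1, an early enzyme of the pathway, differed by -0.70 ± 0.20, the sterol carrier gene Stard4 by -0.48 ± 0.20 and Sc5d by -0.45 ± 0.20, while Insig1, which holds back sterol production, differed by 0.31 ± 0.21. Genes of endoplasmic reticulum and amino acid stress also had a lower median (-0.15, 32 measured, percentile 0.30). Within that list the cystine transporter gene Slc7a11 (-0.80 ± 0.21) and the serine synthesis genes Phgdh (-0.45 ± 0.20) and Psat1 (-0.39 ± 0.20) lay below 0, whereas the stress transcription factor Atf3 (0.59 ± 0.21) and Nupr1 (0.58 ± 0.20) lay above it.

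Of 24 measured TGF-beta and BMP genes, 14 lay below 0, and the median of -0.29 was at percentile 0.27. The members below 0 included Skil (-0.67 ± 0.20) and Tgif1 (-0.63 ± 0.20), repressors of TGF-beta signalling, and the ligands Bmp7 (-0.64 ± 0.20), Tgfb2 (-0.61 ± 0.21) and Tgfb3 (-0.62 ± 0.20). The members past 2-fold went the other way. Tgfb1 was 2.18-fold higher at a low signal (20.4 and 54.0), and Bmp2 was at least 3.86-fold higher. The list did not stand apart with normexp (2.71), with quantile normalization (3.47) or with members measured on both arrays (2.65).

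Hypoxia and glycolysis genes were higher as a list. 3 of 34 measured members were past 2-fold and higher: Ndrg1, a hypoxia-responsive gene with a signal of 5424 in the control and 15823 in the Gli2 shRNA array (2.41-fold), the neuronal glucose transporter Slc2a3 (2.29-fold) and the carbonic anhydrase Car12 (2.25-fold). With normexp Slc2a3 (0.89) and Car12 (0.13) were within 2-fold. P4ha2 (0.97 ± 0.21), Ero1a (0.98 ± 0.20) and Bnip3 (0.95 ± 0.20) fell short of 2-fold. The glycolytic enzymes Ldha (-0.02 ± 0.20, and 0.07 on its other probe) and Pgk1 (-0.03 ± 0.20) were close to 0, and Car9 differed by -0.80 ± 0.23. The median of 0.08 was at percentile 98.3, and the list did not stand apart with normexp (97.2), the stricter filter (95.03), the mean of probes (95.9) or matching on gene density (97.3).

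These 6 lists were those that stood apart among the 28, 5 lower and 1 higher. If the members of each list varied independently, like randomly drawn genes, 1.4 would lie outside the central 95%. Genes of 1 pathway can vary together, which puts more list medians outside, so 6 against 1.4 is not a test. The remaining lists lay within the range of random lists. Directions of lists are relative to other genes: with median scaling the medians of S phase (-0.004), stress (-0.019), GLI target (-0.039) and cholesterol synthesis genes (-0.053) moved close to 0. Such a shift of all genes left the percentiles of the 6 lists that stood apart unchanged.

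**Figure D3:**
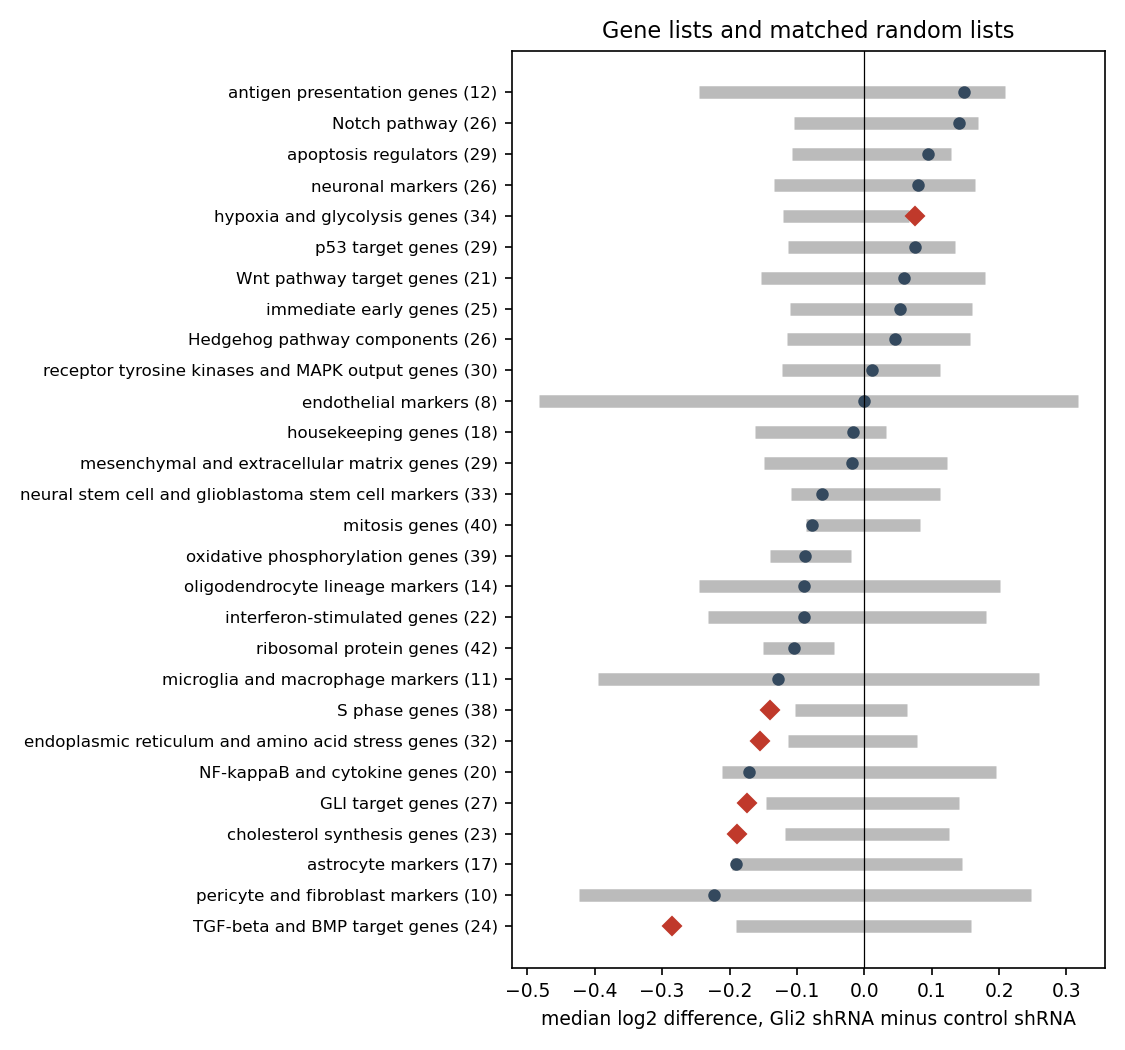
Median log2 difference between the Gli2 shRNA and the control array (horizontal axis) of the 28 gene lists, with the number of measured members in brackets. Grey bars are the central 95% of 10000 random lists matched on expression, circles are lists inside that range and red diamonds the 6 lists outside it, from -0.29 for TGF-beta and BMP target genes to 0.08 for hypoxia and glycolysis genes.

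Genes of p53 and cell death contained single higher members. Btg2, an antiproliferative p53 target, was 2.26-fold higher, and Bbc3, the proapoptotic p53 target also called Puma, was 2.16-fold higher. Cdkn1a, the cell cycle inhibitor p21, differed by 0.63 ± 0.20, and Eda2r was 2.21-fold lower. The p53 list median of 0.07 was at percentile 83.4. In the apoptosis list (median 0.09, percentile 92.0), Bik, a further proapoptotic gene, was at least 2.31-fold higher. That median was -0.05 (percentile 21.1) with the mean of probes and -0.01 (percentile 51.3) without the filter, so the list has no settled direction.

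In other signalling lists, Rbpj, the DNA-binding partner of Notch, was 2.37-fold lower on its brighter probe (-0.69 on the other) while Jag2 was higher, and the Notch list (median 0.14) was at percentile 94.2. The secreted Wnt modulators Dkk3 and Sfrp2 were each 2.85-fold higher, with the Wnt target list at percentile 69.9 (median 0.06). Epha2, an ephrin receptor, was at least 3.19-fold higher in the list of receptor tyrosine kinases and MAPK output (median 0.01, percentile 61.7). Immediate early genes had a median of 0.05 at percentile 66.2.

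Of 20 NF-kappaB and cytokine genes, Vcam1 and Il33 were past 2-fold (median -0.17, percentile 5.29). Of 22 interferon-stimulated genes, Ifi27l2a was 2.70-fold lower and Ifit2 2.22-fold lower (median -0.09, percentile 24.3). Tap2, a peptide transporter of antigen presentation, was 2.30-fold higher among 12 measured genes of that list (median 0.15, percentile 93.0). Sdhd, a subunit of succinate dehydrogenase, was 3.93-fold lower, with a signal of 14449 in the control and 4452 in the Gli2 shRNA array, while none of the other 38 measured oxidative phosphorylation genes was past 2-fold (median -0.09, percentile 43.3).

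Markers of other cell types that a tumour-derived culture could hold were few and dim. 11 microglia and macrophage markers (median -0.13, percentile 33.0), 8 endothelial markers (median -0.00023, percentile 66.9) and 10 pericyte and fibroblast markers (median -0.22, percentile 18.0) were measured. Anpep, a peptidase of pericytes, was 2.02-fold higher. Mesenchymal and extracellular matrix genes had a median of -0.02 (percentile 48.0), ribosomal protein genes -0.10 (percentile 45.3) and housekeeping genes -0.02 (percentile 85.8). List medians from -0.13 to 0 lay above 0 after median scaling, and those lists have no settled direction. Some small positive medians also changed sign. With the mean of probes those of Wnt target genes (-0.07) and Hedgehog pathway components (-0.02) lay below 0. Without the filter those of Wnt target genes (-0.07) and neuronal markers (-0.01) did, so these directions are not settled either.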

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

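Probes without a gene name were left out of the comparisons, and among the 9579 of them measured on both arrays 104 were higher in the Gli2 shRNA array than in the control array by 2-fold or more, and 197 were lower. The highest of these probes was A_51_P479390, with a signal of 43.0 in the control and 1544 in the Gli2 shRNA array (29.6-fold), and the lowest was A_55_P1958400, with 357 and 20.7 (20.9-fold). These probes were singled out after their values were seen, and no explanation was tested.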

How the results depend on the processing

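No paired analysis was possible because each group has 1 array and the result comes from no test. The 2-fold rule gave 67 higher and 100 lower genes with normexp, 769 and 2075 without the filter on dim probes, 874 and 953 at 1.5-fold and 46 and 47 at 3-fold, and the stricter filter gave 159 lower genes. Of the genes called, normexp kept 66 higher and 100 lower, cyclic loess 268 and 206 and median scaling 268 and 176. Scaling on 8 spike-in probes, added after the data had been seen, gave 287 higher and 245 lower. Gli2 was at -0.64 with normexp and below 2-fold with median scaling (-0.90) and cyclic loess (-0.95). The median of the Hedgehog pathway components was 0.18 with median scaling, and that of GLI target genes -0.039 with median scaling and -0.064 without the filter. The percentile of chromosome 6 was 4.29 with normexp and 8.98 without the filter, both added after the data had been seen. The offset of normexp and the shift of median scaling account for part of this by construction, and the cause was not tested otherwise. For the 62 named genes measured on both arrays, 502 alternative values lay within the software error of the value reported, 46 lay outside it, and 0 changed sign among genes past 2-fold. The software error is nearly constant for bright genes, so it serves here as a fixed tolerance and not as a measured spread. Agreement was fixed in advance for part of these values. The filter settings do not change a gene's value, and the mean of probes does not where 1 probe was measured. Median scaling, spike-in scaling and the authors' values shift it by less than the software error of each of these genes. The genes of highest difference were also chosen for a 2-fold difference with normexp. 3 of the 11 alternatives for lists (median scaling, spike-in scaling and the authors' processed values) shift all genes alike and did not move the percentiles of the 6 lists that stood apart. They moved those of some other lists slightly, most of all microglia and macrophage markers, from 32.95 to 34.1 with median scaling. Of the 48 percentiles of the 6 lists that stood apart in the other 8 alternatives, 38 lay outside the central 95%. S phase, cholesterol synthesis and stress genes stood apart in each of these 8, GLI target genes and TGF-beta and BMP genes in 5 and hypoxia genes in 4. Of the other lists, astrocyte markers stood apart in 5 alternatives, mitosis genes in 4, antigen presentation genes in 3, oligodendrocyte markers in 2 and neuronal markers and NF-kappaB genes in 1 each. The stricter filter left too few microglia and endothelial markers for a percentile. Signal over background sets the limit: below a signal of 12.8 on the control array and 15.2 on the Gli2 shRNA array no probe was measured.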

Other observations

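The synaptic, retinoic acid and further astrocyte lists were written after the highest differences had been seen, but before the values of their members. The 2-cell list, the other tests and the choice of chromosomes came after the results had been seen.

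Genes of synaptic vesicles and secretory granules were higher in the Gli2 shRNA array beyond the neuronal markers already described. Without the genes that prompted the list, 22 of 30 measured members lay above 0. Celsr3, an adhesion receptor of axons, was 2.22-fold higher on its brighter probe (-0.26 on the other), the granule genes Scg3 and Vgf were 2.71-fold and 2.08-fold higher (Vgf 0.23 on its other probe), and Syngr3, a synaptic vesicle protein, was 2.38-fold lower. The hypothesis that these genes are higher as a class, which could reflect a shift of part of the culture toward a neuronal or neuroendocrine programme, was met by this list alone: the median of 0.49 was at percentile 100 of matched random lists, and between 98.6 and 100 over the 8 alternatives that do more than shift all genes alike. The size of the median depends on the processing and was 0.07 with normexp. In the neuronal marker list fixed beforehand 16 of 26 genes lay above 0, while others such as Ncam1 (-0.85 ± 0.20) and Map2 (-0.49 ± 0.20) lay below it. That list did not stand apart (median 0.08, percentile 79.4) except with the mean of probes (0.26, percentile 99.9), so a general neuronal shift stays open. The list was written after such genes had been seen at the top of the same arrays, and 1 array per group cannot separate the shRNA from a difference between cultures.

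Cyp26a1 and Cyp26b1, which break down retinoic acid, and Rbp4, a retinol carrier, were 7.29-fold, 3.11-fold and 2.85-fold higher. Among 17 other measured genes of retinoic acid response, Tgm2 was 2.66-fold higher. Rarres2, measured on the Gli2 shRNA array only, was 2.54-fold higher (1.34 ± 0.37). The retinoic acid receptor genes Rarb (0.79 ± 0.20) and Rarg (0.77 ± 0.20) and the retinal reductase gene Dhrs3 (0.79 ± 0.20) fell short of 2-fold. The median of 0.22 was at percentile 99.3, as a higher retinoic acid response would give. The list did not stand apart in 5 of the 8 alternatives that do more than shift all genes alike: the percentile was 93.2 with normexp, 86.3 without the filter, 97.0 with the mean of probes, 47.7 with the stricter filter and 48.8 with members measured on both arrays. With normexp Tgm2 (0.83), Cyp26b1 (0.94), Rbp4 (0.25) and Rarres2 (0.19) were within 2-fold, so whether these genes are higher as a class stays open.

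Several astrocyte genes outside the fixed lists were lower, among them Slc25a18 (3.87-fold), Slc6a11 (2.92-fold) and Chrdl1 (2.92-fold). The hypothesis that astrocyte genes are lower as a class was not met by 37 further astrocyte genes, without the genes that prompted the list, whose median was 0.06, at percentile 91.8. Over the alternatives this list ran from percentile 69.4 without the filter (median -0.03) to 97.9 with the stricter filter (0.14), where it stood apart as higher. The astrocyte markers fixed beforehand went the other way (median -0.19, percentile 2.92, 12 of 17 below 0) and stood apart in 5 of the 8 alternatives that do more than shift all genes alike, so the lists do not agree.

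Besides Tcstv3, genes known from the 2-cell embryo were lower in the Gli2 shRNA array, including AF067061 (13.2-fold) and, among genes that did not prompt the list, Zscan4f (at least 4.69-fold), Zscan4b (at least 3.80-fold) and Usp17la (at least 3.54-fold). 12 such genes were measured, 9 on the control array only and 0 on the Gli2 shRNA array only, against 66.2% on the control side for all genes measured on 1 array. The 5 members at least 2-fold lower had 4 symbol stems (Gm8300, Tcstv, Usp17l and Zscan4), so cross-hybridisation within 1 named family would not cover them all. Within each of several families it could not be tested, because no probe sequences were at hand. Tcstv1 also shares its stem with the prompting gene Tcstv3. The median of -0.70 was at percentile 0.07 of lists matched on expression, where related members such as the Zscan4 genes count as separate genes. Loss of dim signal on the Gli2 shRNA array stays open all the same, because the lower members that did not prompt the list are near the floor. The prompting genes reach higher (Tcstv3 492 in the control, AF067061 204), but they were picked for being lower. Only 3 of the 12 were measured on both arrays, Zfp352 (0.02 ± 0.20), Trim43c (-0.03 ± 0.20) and Sp110 (-0.18 ± 0.20), all within 2-fold, and with these alone or with the stricter filter too few members remained for a percentile. A trend with gene density stays open too. Matched on it, in coarser bins and with 11 members (median -0.46), the list was at percentile 5.73, but with the same members and bins and no density it was already at 4.24, so the call ended before density was matched. A small subset of cells in a 2-cell-like state that is lost from the Gli2 shRNA culture is a possible explanation that was not tested.

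The 2-fold differences as a whole could come from faults of single spots. For the 137 genes past 2-fold with several measured probes this is argued against by their 155 other probes. The median difference of these probes in the direction of the chosen probe was 0.83, with 89.0% going the same way. The 95% exact binomial interval of 83.0 to 93.5% takes probes of 1 gene as independent. Only 36.8% of these probes were past 2-fold themselves, so the sizes are less certain than the directions. The other genes past 2-fold on both arrays, among them Arhgap22, Sst, Tcstv3 and Vcam1, had 1 measured probe and could not be tested. For genes measured on 1 array the question stays open, with 75% of 20 other probes going the same way (50.9 to 91.3%).

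The lists that stood apart may also follow a technical trend. Because the random lists are matched on expression, a first test, whether lists still stood apart after cyclic loess, could hardly have come out otherwise and was dropped. Instead the lists were set against random lists not matched on expression after cyclic loess, which removes a trend with intensity. For GLI target, TGF-beta and BMP and cholesterol synthesis genes the percentiles were at most 0.31. For cholesterol synthesis genes, which also stood apart in each of 8 alternatives, this argues against a bias with intensity as the whole cause. For GLI target and TGF-beta and BMP genes this bias stays open. Against matched lists, GLI target genes were at 6.9 with normexp and 44.8 without the filter. TGF-beta and BMP genes were at 2.71 with normexp and 3.47 with quantile normalization, and their median moved from -0.29 to -0.17 after cyclic loess. For S phase genes (2.37) and stress genes (2.38) the percentiles were within 2 SE (0.31) of the limit of 2.5, and the medians moved from -0.14 to -0.07 and from -0.15 to -0.08, so this bias stays open. A trend with gene density is argued against for these 5 lists by random lists matched on it, with percentiles of at most 1.43 for GLI target, TGF-beta and BMP and cholesterol synthesis genes and at most 0.29 for S phase and stress genes. For hypoxia and glycolysis genes both stay open. That list was at 91.5 after cyclic loess without matching and at 90.5 without either, and at 97.3 when matched on density but at 95.9 with the same coarser bins and no density, so its call rests on the finer bins of expression.

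Of 20 chromosomes, the X chromosome (540 genes), chromosome 6 (803) and chromosome 8 (823) had medians outside the central 95% of random lists whether or not these were matched on gene density. Without matching on gene density 6 of the 20 lay outside, also chromosomes 3 (percentile 0.08), 5 (99.03) and 17 (98.73). Medians outside that range were thus common among chromosomes. The medians were -0.08 at percentile 0 for X, -0.04 at percentile 0.39 for chromosome 6 and 0.04 at percentile 99.97 for chromosome 8. The X chromosome and chromosome 8 stayed outside that range in each of the 8 alternatives that do more than shift all genes alike, whereas chromosome 6 was at 4.29 with normexp and 8.98 without the filter. The directions are relative to other genes: with median scaling the medians of X (0.05) and chromosome 6 (0.09) lay above 0, and without the filter that of chromosome 8 (-0.04) lay below it.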
